A study of Rattus norvegicus with 3 samples.

How the data were processed

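RNA was sequenced from the hippocampus of healthy wild-type rats that received Q808 by gavage for 28 days. Q808 is an anticonvulsant candidate known by its code name. The 3 samples form 1 group, numbered 1 to 3 in their titles, and no untreated sample was analysed here. The labels do not say outright that each sample is a separate animal, so the spread between samples may be partly technical.

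Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was captured on beads and libraries were made with a Vazyme RNA-seq kit followed by conversion for MGI sequencing. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, Cufflinks, HTSeq, DESeq, Bowtie2, StringTie and SAMtools, without versions or roles. The genome build and the strand setting of the counting are not given in the sources used here. Per the file headers, each row carries an NCBI gene identifier, a RefSeq transcript, a product name, Gene Ontology terms and KEGG pathways. The deposited values are raw counts per gene, whole numbers with no normalization, and 1 file belongs to 1 sample. The value columns are headed with the prefix Con_Q and the replicate number. The meaning of that prefix is not given in the sources used here, and group membership was taken from the sample labels alone.

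The 3 files used here differ in extent. That of replicate 2 holds 18560 genes and 15417009 counts. Those of replicates 1 and 3 break off inside a gene row, after 12 and 307 genes that are the first genes of the same alphabetical order. The counts in these last rows stand before the break. They total 11402 and 298642 counts, which are parts of libraries and not depths. The library sizes of replicates 1 and 3 are therefore unknown, and these samples were compared over shared genes alone. The first 307 genes held 1.89% of the counts of replicate 2.

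Gene symbols came from a RefSeq gene table of assembly GRCr8, matched by gene identifier for 17515 of the 18560 genes. The 1045 unmatched genes held 0.353% of counts. No coordinates are given, because the build of the counts is unknown. Of the genes in the table, 17256 were protein coding in RefSeq and 36 were long non-coding RNAs. None of the mitochondrially encoded protein genes was among the rows. No row was a summary line without a gene. Of the listed genes, Tnf, Cyp2b1, Cyp3a23-3a1 and Npy had no row in the table.

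From the deposited counts of replicate 2, counts relative to the library total (CPM) were computed with 95% exact Clopper-Pearson intervals. These cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, which was 0.195 CPM. CPM is not corrected for transcript length, so levels of different genes are ranks of read yield and not of molecules. Reads of near-identical genes (hemoglobin chains, actins, Abcb1a and Abcb1b, ribosomal protein genes) and of overlapping genes could not be told apart further than the authors' counting did.

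A gene with at least 10 counts was called detected. For each of 30 gene lists (14 functional, 16 of cell types or regions), the median of log2(CPM + 1) over detected members was ranked among 10000 random lists of the same size drawn from detected genes. A list was said to lie above or below the random range when it fell outside the central 95% of these. This describes 1 library and carries no p-value. For replicates 2 and 3, counts were scaled by edgeR's TMM factors over shared genes with at least 10 counts in each. The biological coefficient of variation was edgeR's common estimate from a model with an intercept only, with a 95% interval from 200 resamplings of the genes. Each gene's counts were compared by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the genes tested. That test was chosen after the counts had been examined, covers counting error only, and compares the 2 libraries and not conditions. The design assumed 3 complete samples, and levels were taken from replicate 2 alone instead. Over the 7 genes with at least 10 counts in all samples, replicates 1 and 3 did not differ beyond counting noise in a chi-square test while both differed from replicate 2, so as a precaution their mean was used as 1 sample in means and SDs. The test on 7 genes does not show that they are 1 library. Spreads with 3 separate samples are given as well.

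The lists, the detection minimum and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the most counts, the 2 highest members of each list, and the 10 genes with the largest ratio between libraries among those with a mean of at least 100 counts. Some genes that the rule selects are not reported here. The choroid and vessel genes tested in the closing section were chosen before their values were seen, and the 12 genes held by all files are named for that reason. Any other gene named was chosen after its values were seen. Alternatives were other minimums (1 and 50 counts), no filter, DESeq2 size factors, a pseudocount of 0.1, a background of all genes with undetected members counted, and leaving out each replicate. Comparisons planned on a table of the authors' own fold changes were not made, because no such table was used here.

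The procedures were tested on simulated data. For replicates 2 and 3 over 243 genes, coefficients of variation set to 0.05, 0.1 and 0.2 were estimated at medians of 0.0508, 0.100 and 0.201. In the same comparison, the binomial test recovered 82.5% of 30 genes changed 1.5-fold and 95.7% of those changed 2-fold. False calls averaged 1.45 and 1.3 over 20 runs. These rates hold for the simulated counts, while the real libraries differed beyond counting noise. Of 100 random lists of 20 genes from the 14295 detected genes of replicate 2, 5 fell outside the central 95%. All 100 lists drawn from highly expressed genes lay above it, which follows largely from how they were drawn. Sensitivity to lists of moderate level was not tested. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.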

Results

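Hippocampal gene expression was measured by RNA sequencing in 3 samples from healthy rats given Q808 by gavage for 28 days. The file of replicate 2 held 18560 genes with a total of 15417009 counts. The files of replicates 3 and 1, as used here, held the first 307 and 12 of these genes, so their depth is unknown. The labels describe all samples as treated, so no value measures a change caused by Q808. The count columns are headed Con_Q, and whether this prefix refers to a control is not known. If it did, the levels would not be those of treated hippocampus. Levels across the whole transcriptome come from replicate 2 alone and have no replicate check. For the 65 genes that the naming rule selects there, the 95% counting interval reached at most 10.3% from the value.

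The transcriptome of replicate 2 was led by myelin, lipid and neuronal genes. Mbp, which encodes myelin basic protein, had the most counts at 5578 CPM (95% interval 5541 to 5615). It was followed by Apoe, the lipid carrier made largely by astrocytes, at 3482 CPM. The sodium pump subunit gene Atp1b1 stood at 2952 CPM. The neuronal genes Ncdn and Snap25 reached 3207 and 2479 CPM, and Zwint reached 3025 CPM. The lipid desaturase gene Scd2 (2804 CPM) and the peptide-processing gene Cpe (2633 CPM) were also among the 10 highest. The 10 highest genes took 3.27% and the 100 highest took 15.9% of the counts in the table. At least 10 counts were found for 14295 genes (77.02%), 2431 genes reached 100 CPM, and 1703 genes had no count.

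The cell type lists asked which cells the tissue piece contained. All 10 listed neuron markers were detected, with a median of 688 CPM, above every one of 10000 random lists of the same size. Snap25 and Syt1, both part of the synaptic release machinery, were the highest. All 10 astrocyte markers (median 456 CPM) and all 10 oligodendrocyte markers (median 333 CPM) were detected at the same percentile of 100. Among astrocyte genes the calcium-binding protein gene S100b reached 1170 CPM and Aldoc, a glycolytic enzyme gene, reached 826 CPM. Oligodendrocyte precursor markers had a median of 41.4 CPM, with the transcription factor genes Olig1 at 197 CPM and Sox10 at 73.1 CPM. Microglia and macrophage markers (median 24.97 CPM) lay at the 49.4th percentile, with the lysosomal protease gene Ctss at 130 CPM. Endothelial and mural markers (median 15.6 CPM) lay at the 22.4th percentile, with the glucose transporter gene Slc2a1 at 140.3 CPM and the tight junction gene Cldn5 at 84.1 CPM.

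Markers of the hippocampal fields were present together. The granule neuron list lay at the 98.8th percentile, with a median of 113 CPM over 6 detected members, led by Stxbp6 (160.0 CPM) and the dentate transcription factor gene Prox1 (136 CPM). The CA3 and CA2 list lay at the 99.6th percentile over 8 detected members of 9, the other having no count. It was led by Chgb at 826 CPM and Cpne4 at 276 CPM. How specific each listed gene is to its field was not tested. The CA1 list, led by Mpped1 (232 CPM) and Wfs1 (190.2 CPM), lay on the upper limit of the central 95% of random lists and was not counted as outside it, but lay above it with all genes as the background. Interneuron markers lay inside the range at the 92.4th percentile, and above it with all genes as the background (98.0th), with Gad1, the GABA-synthesizing enzyme gene, at 363 CPM and the peptide gene Cck at 255 CPM.

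Lists of neighbouring tissues were lower. The thalamus list (median 13.7 CPM) was led by Plekhg1 at 43.1 CPM and by the vesicular glutamate transporter gene Slc17a6 at 26.1 CPM. The striatum list (median 9.92 CPM) was led by Ppp1r1b at 105 CPM and the enkephalin gene Penk at 32.3 CPM. The neocortex list (median 28.0 CPM) was led by Lamp5 at 57.0 CPM and Cux2 at 38.1 CPM. All of these lay inside the central 95% of random lists, as did the leptomeninges and fibroblast list (2.86th percentile), where Ptgds, a prostaglandin synthase gene, had 306 CPM and Igf2 had 75.7 CPM. The blood list (median 2.04 CPM) and the choroid plexus and ependyma list (median 3.24 CPM) lay below the central range of lists drawn from detected genes, and inside it when all genes were the background. The granule neuron list also fell inside it when, in addition, its undetected members were counted. Single members stood well above those medians. The hemoglobin genes Hba-a1 and Hbb had 127 and 67.3 CPM, Ttr, the transthyretin gene expressed strongly by choroid plexus, had 176 CPM, and Enpp2 had 129 CPM.

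**Figure D1:**
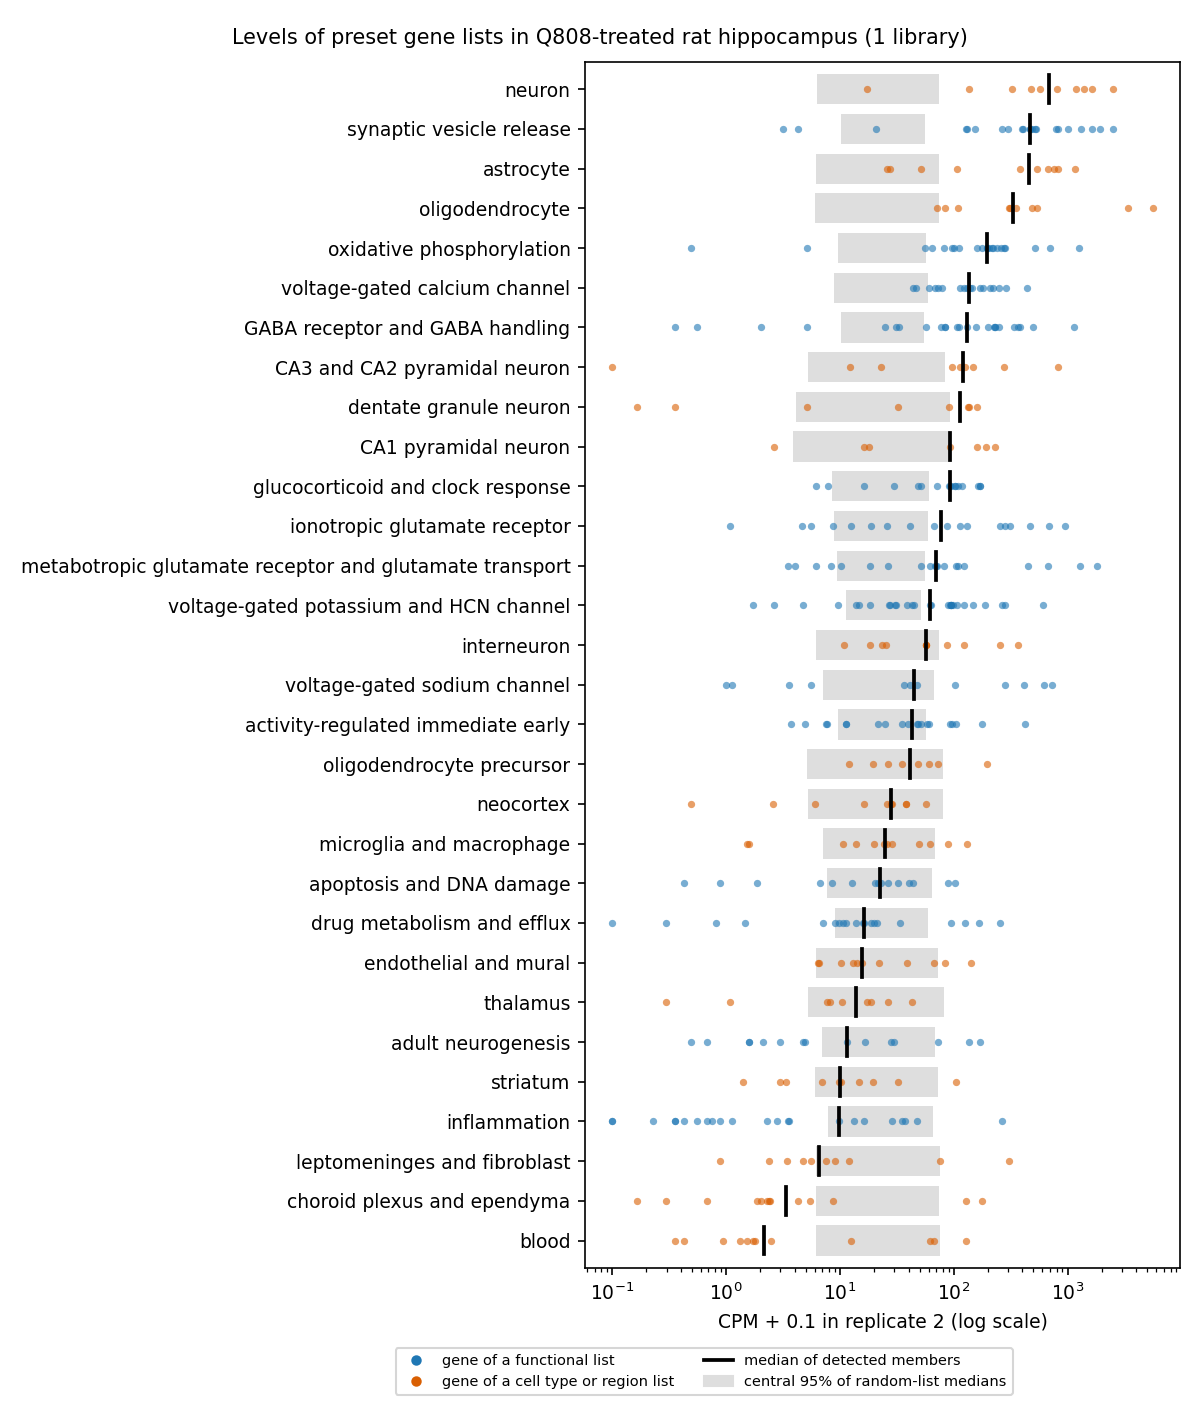
Levels of 30 preset gene lists in replicate 2, with 1 point per gene on a log axis of CPM plus 0.1, a black bar at the median of detected members and a grey band for the central 95% of random-list medians. Neuron (688 CPM), synaptic vesicle (467 CPM), astrocyte (456 CPM) and oligodendrocyte (333 CPM) medians lie highest, while choroid plexus (3.24 CPM) and blood (2.04 CPM) lie below the band.

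Genes of inhibitory and excitatory transmission, the usual targets of anticonvulsants, were read at high levels. Of 25 GABA receptor and GABA handling genes, 23 were detected with a median of 131 CPM, above all random lists. The metabotropic receptor gene Gabbr1 reached 1138 CPM, while Gabra6 and Gabre stayed under 10 counts. All 18 ionotropic glutamate receptor genes were detected, with a median of 76.7 CPM at the 99.6th percentile. Gria2, an AMPA receptor subunit gene, had 949 CPM and Grin1, the obligatory NMDA receptor subunit gene, had 678 CPM. The list of metabotropic receptors and glutamate transport lay at the 99.4th percentile, with the vesicular transporter gene Slc17a7 at 1796 CPM and the glutamine synthetase gene Glul at 1276 CPM. Genes of synaptic vesicle release were higher still, with a median of 467 CPM, 19 of 22 members at or above 100 CPM, and Snap25 and Syp (1929 CPM) in front.

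Ion channel lists differed in rank. The calcium channel list lay at the 99.99th percentile with a median of 135 CPM and all 18 members detected, led by Cacna1e (440.1 CPM) and Cacna2d1 (287 CPM), the latter encoding a subunit bound by gabapentin. The potassium and HCN channel list lay at the 99.4th percentile with a median of 61.5 CPM and all 29 members detected. The sodium channel list (median 44.5 CPM, 85.3rd percentile) did not lie outside the range of random lists. Its highest member was the auxiliary subunit gene Scn3b (727 CPM).

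Among the remaining functional lists, 2 lay above the random range. The oxidative phosphorylation list had a median of 196 CPM over 21 detected members of 22. Atp5f1b had 1257 CPM and Atp5f1a had 700.0 CPM, while Ndufa1 had 6 counts. The glucocorticoid and clock list lay at the 99.9th percentile with all 17 members detected, led by Zbtb16 (170.2 CPM) and the mineralocorticoid receptor gene Nr3c2 (169 CPM). Activity-regulated genes (median 43.2 CPM) lay inside the range, and above it with all genes as the background (98.3rd percentile), with the neurotrophin receptor gene Ntrk2 at 418 CPM and Jun at 176 CPM. Of 23 measured inflammation genes, 8 were under 10 counts, and the detected ones had a median of 9.73 CPM at the 5.06th percentile. The antigen presentation gene B2m had 264 CPM and Stat3 had 47.1 CPM, while Il6 and Ccl2 had no count, which allows up to 0.195 CPM each. Drug metabolism and efflux genes (median 16.0 CPM) were led by Cyp46a1, the brain cholesterol hydroxylase gene, at 255 CPM and Gstm1 at 166 CPM. The apoptosis and DNA damage list (median 22.2 CPM) was led by Bcl2l1 at 101 CPM and Parp1 at 88.2 CPM. The adult neurogenesis list (median 11.4 CPM) was led by Neurod2 at 168 CPM and Prox1. The last 3 lists lay inside the random range. In all, 13 of the 30 lists lay above it, 2 below and 15 inside.

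The spread between replicates was measured over shared genes. Replicates 2 and 3 shared 307 genes, of which 243 had at least 10 counts in each. Across these genes, which are not independent replicates, log2 levels had a Pearson correlation of 0.982 and a Spearman correlation of 0.984. After scaling, 167 genes (68.7%) lay within 1.2-fold of each other and 7 differed by more than 2-fold. The common biological coefficient of variation was 0.170 (95% interval 0.110 to 0.225). Their counts differed by a chi-square of 12.6 per degree of freedom, where simulated counting noise gave 0.838 to 1.19.

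The largest ratio was that of Ace, the angiotensin-converting enzyme gene, with 101 counts in replicate 2 and 877 in replicate 3. This was 8.40-fold higher in replicate 3 (95% counting interval 6.83 to 10.4). Among the other genes with a mean of at least 100 counts, the extracellular matrix genes Adamtsl4 and Adamts1 were 4.38-fold and 2.34-fold higher in replicate 3, and Adam1a was 1.99-fold higher. Abhd2 (1.62-fold), Abhd14a (1.59-fold), Abat, the GABA-degrading transaminase gene (1.51-fold), and Adamtsl1 (1.48-fold) were also higher in replicate 3. Acbd4 and Adamts10 were 1.63-fold and 1.53-fold higher in replicate 2. All 10 passed the exact binomial test between these libraries, with adjusted p of 0.00534 or less. In total 82 of 243 genes did, 41 higher in each library. With 1 library on each side, the test and its p-values cover counting error only and not the spread between samples. The even split of directions is largely set by the scaling, which centres the ratios of these same genes. Each direction is thus relative to the other shared genes. Other members of preset lists differed less. The efflux transporter genes Abcb1a (0.935-fold, 0.825 to 1.06) and Abcg2 (1.17-fold, 0.940 to 1.47) did not pass the test, and Abcc1 was 1.33-fold higher in replicate 3 (adjusted p = 0.00333, exact binomial test).

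**Figure D2:**
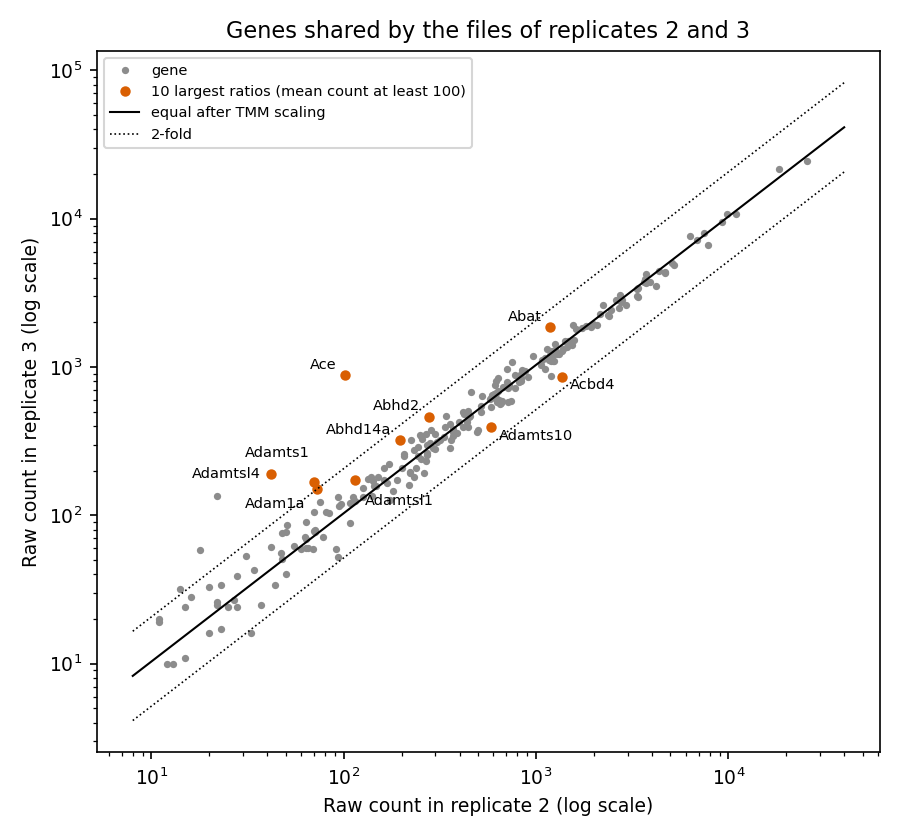
Raw counts of 243 genes in replicate 2 (horizontal) and replicate 3 (vertical), both on log axes, with a solid line for equality after scaling, dotted lines at 2-fold and in orange the 10 largest ratios among genes with a mean of at least 100 counts. Most genes follow the line, and Ace lies farthest from it at 8.40-fold.

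Only 12 genes were held by the files of all 3 samples, and 7 of them had at least 10 counts in each. Over these 7 genes, replicates 1 and 3 agreed within sampling noise (chi-square of 1.37 per degree of freedom), while replicate 2 differed from them by 3.48 and 4.42. So few genes cannot show whether replicates 1 and 3 are separate libraries. As a precaution they were counted as 1 sample in the means below, and values with 3 separate samples are given beside the spread. Aak1, which encodes a kinase of clathrin-mediated endocytosis, had a scaled count of 7423 ± 126 (SD, n = 2). Aacs, encoding acetoacetyl-CoA synthetase, had 748 ± 19.7, Aaas, a nucleoporin gene, had 331 ± 9.26, Aagab had 1307 ± 95.9 and Prxl2c had 446 ± 35.1 (SD, n = 2 each). Aadat, an aminotransferase gene of the kynurenine pathway, had 144 ± 31.8, and A3galt2 had 20.2 ± 7.52 (SD, n = 2 each). Coefficients of variation ranged from 1.70% to 37.2% with a median of 7.34%, and with 3 separate samples from 2.19% to 42.1% with a median of 6.10%. For Aak1 they were 1.70% and 2.63% respectively. With 3 separate samples, Aacs (2.19%) and Aaas (2.43%) lay below the 3.67% and 5.52% that counting alone gives. The other genes lay above: Aadat (17.6% against 8.13%), Aagab (6.10% against 2.79%), Aak1 (2.63% against 1.16%), Prxl2c (8.11% against 4.78%) and A3galt2 (42.1% against 21.3%). A1bg, A2m, A2ml1, A4galt and A4gnt had 6 counts or fewer in every sample. These 12 genes give no general measure of the spread of replicate 1.

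**Figure D3:**
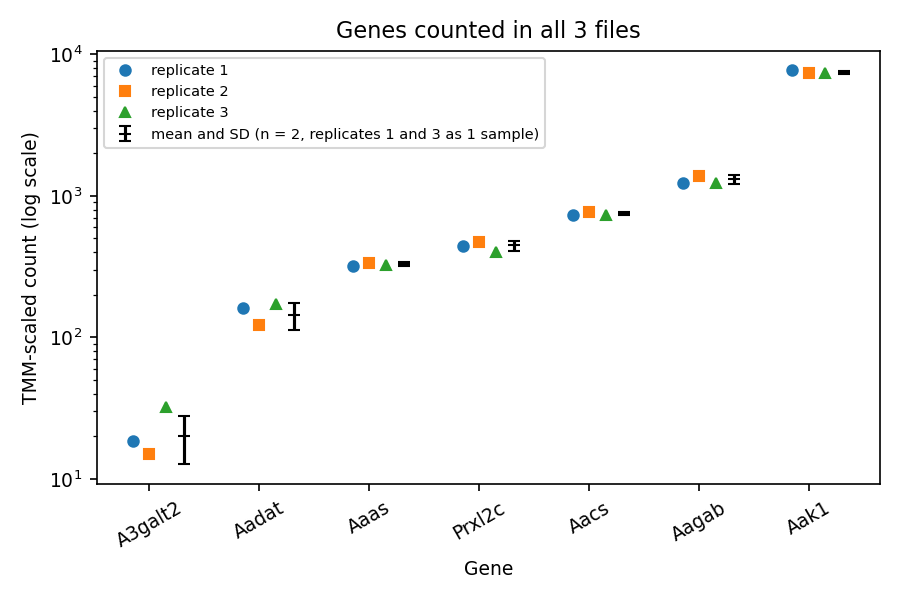
Scaled counts of the 7 genes with at least 10 counts in all 3 replicates, on a log axis, with 1 symbol per replicate and in black the mean and SD with replicates 1 and 3 as 1 sample (n = 2). The replicates of Aak1 lie close together, although their 2.63% with 3 separate samples exceeds the 1.16% that counting alone gives. Those of A3galt2, the gene with the fewest counts, lie farthest apart (42.1% with 3 separate samples, where counting alone gives 21.3%).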

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

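Detected genes in replicate 2 numbered 16857 at 1 count and 12068 at 50 counts, against 14295. With pseudocount 0.1, none of the 30 lists changed side of the random range. With all genes of the table as the background and undetected members counted, 6 did, although the number outside stayed at 15. The activity-regulated (98.3rd percentile), CA1 (99.1st) and interneuron (98.0th) lists then lay above the range. The granule neuron (95.9th), choroid plexus (8.63rd) and blood (5.58th) lists then lay inside it. In this setting 22 of the 30 percentiles were higher and 2 lower, and 24 moved beyond their sampling interval. With that background and detected members only, an alternative chosen after seeing the data, 24 percentiles were higher and none lower, 16 lists lay outside, and 5 changed side. The granule neuron list (99.5th) then stayed above, so its fall came from its undetected members. The Pearson correlation of replicates 2 and 3 was 0.967 with no filter, against 0.982. Their coefficient of variation was 0.169 with DESeq2 size factors, 0.184 with no filter and 0.135 without Ace, the last chosen after seeing the data. The number of differing genes ranged from 80 to 85 over other scalings and no filter, also chosen afterwards. Over the 7 genes of all 3 samples, the coefficient of variation was 0.0379, and leaving out 1 sample moved it over 1.5-fold: 0.0808 without replicate 1, 0.0206 without replicate 2 and 0.0619 without replicate 3. It was 0.0726 with replicates 1 and 3 as 1 sample, an alternative also chosen afterwards. Leaving out replicate 2 ends every transcriptome-wide value. No paired analysis was possible because all samples belong to 1 group. Alternatives planned for a table of the authors' comparisons were not run.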

Other observations

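The tests on pathways, gene pairs, Y-linked genes, second gene models and the counts without Ace were chosen only after the results were seen. The choroid and vessel tests on replicate 3 were chosen after the ratio of Ace was seen, before the values they measure. By the files' own KEGG annotation, 286 pathways had at least 15 detected genes in replicate 2. Of these, 82 lay above and 51 below the central 95% of 2000 random lists, and the pathways share many genes. Among those above were the synaptic vesicle cycle (median 216 CPM over 56 genes), GABAergic synapse (154 CPM over 77 genes) and oxidative phosphorylation (117 CPM over 105 genes). Among those below were neuroactive ligand-receptor interaction (8.89 CPM over 181 genes) and cytokine-cytokine receptor interaction (7.65 CPM over 115 genes).

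Within gene families some members took most of the counted reads, with intervals that cover counting error only and no correction for transcript length. How completely reads were assigned to each gene was not tested, so these are ratios of counts and not of expression. Among sodium channels, Scn2a had 6.82 times the counts of Scn1a (6.27 to 7.42) and 2.77 times those of Scn8a (2.62 to 2.94). Grin2b had 6.94 times the counts of Grin2a (6.50 to 7.41). Slc17a7 had 68.7 times the counts of Slc17a6 (62.3 to 76.0). Slc1a3 had 13.2 times the counts of Slc1a2 (12.2 to 14.2), the main glial glutamate transporter gene of the forebrain, which had only 51.0 CPM. Gad1 had 6.44 times the counts of Gad2 (5.99 to 6.92). The Y-linked genes Ddx3y (1465 counts), Eif2s3y (1237 counts) and Kdm5d (615 counts) were read in replicate 2, while Uty had 8 counts, and the labels used here give no sex.

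Choroid plexus markers were found in the hippocampus of replicate 2. Ttr had 176 CPM, although the median of the preset choroid plexus and ependyma list was low, and 6 of 7 choroid markers reached 10 counts, among them Clic6 (64 counts), Folr1 (36) and Kl (34), while Tmem72 had 9. This leaves carry-over of choroid plexus in the dissected piece open. Of 7 random genes of the table, at least 6 reach 10 counts in 49.7% of draws, so the number of markers reached says little. That figure does not cover the level of Ttr, and expression of these markers in other hippocampal cells was not tested. No biological explanation was tested, since the design has 1 group.

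Counts of replicates 2 and 3 differed by a chi-square of 12.6 per degree of freedom, and by 10.2 without Ace. Simulated counting noise gave 0.838 to 1.19. This argues against counting noise alone over the 243 genes, and does not show what else made these libraries differ. Ace is abundant in choroid plexus, which prompted the hypothesis that replicate 3 held more of it. Abca4, set down as choroid-enriched before its values were seen, was 5.89-fold higher in replicate 3, on 22 and 134 counts. Its 95% interval of 3.07 to 11.3 adds the common coefficient of variation of 0.170 to counting error. That coefficient came from these same 2 libraries over all 243 genes. The interval therefore does not measure how Abca4 itself varies between samples. Besides Ace, no other shared gene was tested as a choroid marker. Of 5 vessel genes, Abcb1a, with 515 of their 1062 counts in replicate 2, stood at 0.935-fold. Abcb1b, Abcg2, Acta2 and Acvrl1 stood at 1.17-fold to 1.26-fold. Together the 5 genes were 1.08-fold higher (0.833 to 1.41, an interval built in the same way), far from the change in Ace. This argues against an increase of blood vessel in replicate 3 as large as that of Ace, and leaves a small one open. More choroid plexus may therefore account for Ace and Abca4, but it rests on these 2 genes and leaves the other differing genes open, and no biological explanation was tested.

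Counts of 76 cytosolic ribosomal protein genes were uneven in replicate 2, where Rpl4 had 451 CPM, while Rpl8 had no count, Rpl35a had 1 and Rps6 had 4, although these proteins are made in equal numbers for each ribosome. If reads shared with pseudogenes were the cause, genes with more annotated copies should have lower counts. Spearman's rho across the genes was 0.134 (two-sided permutation p = 0.250, 95% interval -0.0909 to 0.366), which leaves this open because the interval includes both signs. Another gene model of like name with at least 500 counts was seen for 1 of the 5 genes under 10 CPM, an Rpl35a-like gene with 687 counts. The same held for 5 of the 71 other genes (Fisher's exact test, p = 0.345). That minimum left out an Rpl8-like gene (145 counts against 0) and an Rps6-like gene (108 against 4). An Rpl7a-like gene had 17 counts against 52, and Rplp2 had no other gene of like name. These smaller counts were compared afterwards and not tested. Like names do not separate second models from distinct paralogs. Neither explanation can be settled from counts alone, no biological explanation was tested, and these genes' levels are uncertain. Low counts of genes outside this family, such as Ndufa1 with 6, were not examined in this way.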
